A study of Mus musculus with 8 samples.

How the data were processed

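RNA was sequenced from 2 mouse B cell lymphoma lines, #1.1 and #1.2, that arose in Eμ-Myc mice of the C57BL/6 strain. Eμ-Myc mice carry a Myc transgene under the enhancer of the immunoglobulin heavy chain locus and develop B lineage lymphomas. The cells were cultured for 2 h with 250 nM JQ1, a small molecule that displaces the BET proteins from acetylated chromatin, or with its solvent DMSO. Each of the 4 groups held 2 libraries, 8 in all, and the group of each library was taken from its labels. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

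Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the authors used FastQC, cutadapt 1.7, TopHat, Bowtie2, HTSeq and limma with the GRCm38 (mm10) mouse genome. The annotation release, the strand setting of the counting and the other versions are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies, such as Hspa1a and Hspa1b, the immunoglobulin V genes and the histone genes, may have lost or shared reads, and their values are uncertain to that extent. The file counts by gene, so transcripts of the Myc transgene and of the endogenous Myc gene are summed.

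The deposited values are counts of reads per Ensembl gene, whole numbers that the authors did not normalise. The file holds 43629 genes, of which 42462 were matched to a symbol by identifier. It also holds 5 summary lines of HTSeq that name no gene. These were left out of library sizes and tests. Reads assigned to no gene were 12.3 to 14.4% of the reads in the file, reads that fitted more than 1 gene were 1.54 to 1.67%, and the other 3 summary lines were 0. Gene counts summed to between 10347453 and 13049877 reads per library. Coordinates and gene classes are from GENCODE mouse release M21, which uses the same GRCm38 build.

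From these counts, everything else was computed here in R 4.3.3. edgeR 4.0.16 tested 12413 genes kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15). Libraries were scaled by TMM, and CPM below is edgeR's count per library size after this scaling. A model of 4 group means was fitted to all 8 libraries, which left 4 residual degrees of freedom, and contrasts were tested two-sided with edgeR's quasi-likelihood F test. All adjusted p-values of genes are Benjamini-Hochberg values from this test over all genes tested, with a threshold of 0.05. The contrasts were the JQ1 effect averaged over both lines, the JQ1 effect in each line, the difference of these effects (interaction), and line 1.2 minus line 1.1 in DMSO. Fold changes are log2 with a standard error (SE) derived from the F statistic. They are relative to the counts of each library, so a change in total mRNA per cell would not show. Group values are mean CPM ± SD of 2 libraries.

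Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the lists. Of 26 lists, 22 had at least 3 tested members. camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the 4 residual degrees of freedom, so it has little power here whatever the correlation.

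The genes named in the text follow a rule. For the averaged JQ1 effect these were the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold. They needed a mean of at least 5 CPM, a symbol that is not a clone, pseudogene or identifier, and in each line both JQ1 libraries on the same side of both DMSO libraries. For the interaction they were up to 5 genes each way, and for the line difference 6 each way with both libraries of a line above both of the other. From each list came up to 4 members with the smallest p and a mean of at least 1 CPM. Cd274, Myc, Mycn, Hexim1, Brd2, Brd3 and Bcl2 were always included. Some genes that the rule names are not reported here. The lists, this rule, the tests and the alternatives below were fixed before the data were examined. An alternative with the level of Gm42418 as a covariate in all comparisons was added after seeing the data. It had for a time been narrowed to the interaction once its outcomes were known, which was undone, and it covers the counts, the named genes, the lists for the averaged effect and the correlation between lines.

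The alternatives were other scalings (DESeq2's size factors, upper quartile, library totals), DESeq2 1.42.0 and limma-voom in place of edgeR, no filter on low counts and a stricter one (at least 5 CPM in at least 2 libraries), an additive model, fits of only the 4 libraries compared, replicate blocks, each library left out in turn, a test against a fold change of 1.5, and a threshold of 0.01.

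The edgeR fit was tested on simulated data, with counts drawn from the real means and library sizes and 50 genes changed at each fold size. Over 12121 genes, the averaged JQ1 comparison recovered 56% of genes changed 1.2-fold, 81.2% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 10 false calls among 11924 unchanged genes. The interaction made 0 false calls, but no interaction effect was simulated, so its recovery is not known. Far fewer genes were changed in the simulation than were called in the data (62%), so the rates may differ there. Before averaging, replicates were compared by a chi-square test over genes. The statistic per degree of freedom was 4.77 in line 1.1 DMSO, 1.46 in line 1.1 JQ1, 1.96 in line 1.2 DMSO and 2.38 in line 1.2 JQ1, so each pair differed by more than the sampling noise and every library was counted. The common biological coefficient of variation was 3.5%.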

Results

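Gene expression was measured in Eμ-Myc lymphoma lines 1.1 and 1.2 after 2 h in 250 nM JQ1 or in DMSO, with 2 libraries in each of the 4 groups. Between 17278 and 17738 genes per library had at least 1 read. In a principal component analysis of log2 CPM, the first component held 65.4% of the variance and separated JQ1 from DMSO libraries. The second held 16.1% and separated the lines. Markers of other cell types were rare. None of the 10 NK cell markers and none of the 8 erythroid markers in the file passed the expression filter. Of 14 T cell markers, 2 passed (Cd2 and Cd6), of 14 myeloid markers 4 passed with a mean of at most 6.57 CPM, and of 11 stromal markers 2 passed, with Pecam1, an adhesion receptor also found on B cells, at 55.3 CPM.

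The first comparison asked which genes respond to BET bromodomain inhibition in both lines. JQ1 changed a large part of the transcriptome within 2 h. Averaged over the lines, 7692 of 12413 genes (62%) passed the threshold, 3809 higher and 3883 lower. Most changes were small, with a median absolute log2 change of 0.39, and 438 genes rose and 729 fell at least 2-fold. The genes with the largest rise included Tspoap1, which went from 7.51 ± 0.74 CPM to 245 ± 11 CPM in line 1.1 and from 17.4 ± 1.6 to 278 ± 19 CPM in line 1.2 (SD, n = 2). Its averaged log2 change was 4.51 ± 0.057 (SE), with an adjusted p of 5.62e-26 from edgeR's quasi-likelihood test. The histone genes Hist1h1c, Hist1h2bc and Hist1h2bl rose by 3.98, 3.55 and 2.96 on the log2 scale. The other 8 genes with the largest rise were Mpzl1, the WNT receptor gene Fzd5, the mitochondrial carrier gene Slc25a18, the magnesium transporter gene Cnnm4, the autophagy gene Trp53inp2, Ccnyl1, Pdlim7 and Sil1, with log2 changes from 3.11 (Mpzl1) to 2.27 (Sil1).

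Il7r, the interleukin-7 receptor of early B cells, fell from 120 ± 6.1 to 6.5 ± 0.16 CPM in line 1.1 and from 92.1 ± 4.6 to 5.83 ± 0.59 CPM in line 1.2 (SD, n = 2), an averaged log2 change of -4.09 ± 0.067 (SE, edgeR adjusted p = 7.99e-24). Sla, an adaptor that dampens antigen receptor signalling, changed by -4.86 ± 0.20 and Thbd, the thrombomodulin gene, by -4.28 ± 0.081. The potassium channel gene Kcnn4 changed by -3.65, the receptor genes Gpr18, Lgr5, Cysltr1 and P2ry10b by -3.33, -3.27, -3.24 and -3.23, and Il2ra, the interleukin-2 receptor alpha chain, by -2.88. Kctd14, the histone deacetylase gene Hdac9 and Fam169b changed by -3.03, -3.01 and -2.94.

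**Figure D1:**
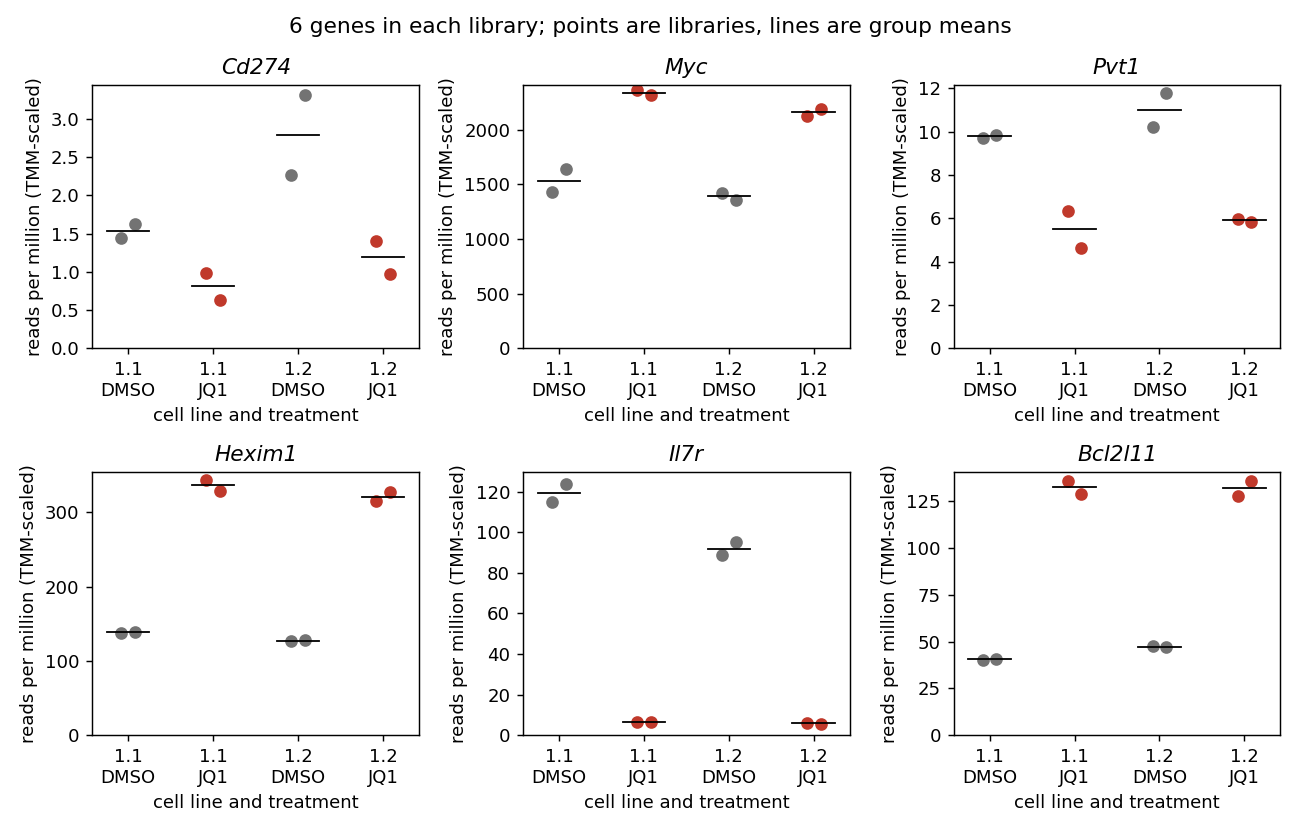
CPM (TMM-scaled, linear axes from 0) of 6 genes in each library, by cell line and treatment. Points are libraries (grey, DMSO; red, JQ1) and lines are means of 2 libraries. Cd274, Pvt1 and Il7r are lower and Myc, Hexim1 and Bcl2l11 higher in every JQ1 library than in the DMSO libraries of the same line.

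The title of the series names PD-L1, the T cell inhibitory ligand encoded by Cd274. Cd274 (chromosome 19, 29367455 to 29388095) was lower after JQ1, from 1.53 ± 0.13 to 0.815 ± 0.25 CPM in line 1.1 and from 2.78 ± 0.75 to 1.19 ± 0.31 CPM in line 1.2 (SD, n = 2). The averaged log2 change was -1.05 ± 0.26 (SE, edgeR adjusted p = 0.00117). The gene had 7 to 40 reads per library, so its level rests on few reads. Within a line, the change of -1.23 ± 0.33 in line 1.2 passed the threshold (adjusted p = 0.00336) and that of -0.88 ± 0.41 in line 1.1 did not (adjusted p = 0.0727), while the difference between these effects had an adjusted p of 0.913. The averaged change did not pass a test against a fold change of 1.5. It also lost its call (-0.93) with the level of Gm42418 as a covariate, an alternative chosen after seeing the data.

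Cd274 was not alone among the genes through which other immune cells read a lymphoma cell. Of 15 measured checkpoint and costimulatory ligands and receptors, 11 fell, 1 rose and 3 did not pass the test, with a median log2 change of -0.92. Btla, an inhibitory receptor of lymphocytes, fell by 2.62 on the log2 scale, Cd48 by 1.004, Cd47, which signals to macrophages not to engulf the cell, by 0.96, and the abundant Cd24a by 0.46. The riser was the adhesion ligand gene Icam1 (0.74). Of 19 measured interferon response genes, 13 fell, 3 rose and 3 did not pass, with a median of -0.90. Parp14 fell by 2.45, its partners Dtx3l by 1.69 and Parp9 by 0.98, and Samhd1 by 0.54. Both lists passed in camera with the preset correlation (adjusted p = 0.00205 for the ligands and 0.00374 for the interferon genes) but not with an estimated correlation (adjusted p = 0.085 for each).

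Antigen presentation genes moved both ways. For MHC class I, 6 of 21 genes rose and 10 fell, with H2-K1 at 0.53 and the chaperone gene Calr at 0.51 against the peptide transporter gene Tap2 at -0.99 and the peptidase gene Erap1 at -0.65. For MHC class II, 1 of 11 rose and 5 fell, among them the class II regulator gene Rfx5 (-0.95), H2-Ob (-0.72), H2-Ab1 (-0.46) and Ctss (-0.40). Neither list passed in camera (adjusted p = 0.612 and 0.138).

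Myc (chromosome 15, 61985391 to 61990374), the oncogene of these lymphomas, was among the most abundant transcripts and rose after JQ1. It went from 1530 ± 150 to 2340 ± 26 CPM in line 1.1 and from 1390 ± 47 to 2160 ± 45 CPM in line 1.2 (SD, n = 2). The averaged log2 change was 0.62 ± 0.036 (SE, edgeR adjusted p = 2.06e-13), a 1.54-fold rise that did not pass a test against a fold change of 1.5. Mycn had 0 reads in all 8 libraries, which allows at most 0.23 to 0.29 CPM (3 reads per library, counting error only). Of 60 measured MYC target genes, 14 rose and 25 fell, with a median of -0.02, and the list did not pass in camera (adjusted p = 0.19), but did without line 1.1 DMSO replicate 2 (adjusted p = 0.0375). With all libraries it had an adjusted p = 0.731 with an estimated correlation. The ribosome biogenesis genes Ppan (-0.60) and Wdr43 (-0.41), the folate transporter gene Slc19a1 (-0.76) and Srm (-0.49), which makes spermidine, were among those that fell.

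Several genes of transcription elongation rose. Hexim1, which encodes an inhibitor of the elongation kinase P-TEFb, rose from 139 ± 0.61 to 337 ± 11 CPM in line 1.1 and from 128 ± 0.7 to 321 ± 8.6 CPM in line 1.2 (SD, n = 2), by 1.30 ± 0.034 on the log2 scale (SE, edgeR adjusted p = 6.65e-20). Brd2 rose by 0.99 ± 0.033, while Brd3 was at -0.001 ± 0.038 and did not pass. Polr2a, the largest subunit of RNA polymerase II, rose by 1.14 and Mepce, which caps the RNA that holds P-TEFb inactive, by 0.95. In the whole list, 11 of 24 genes rose and 7 fell. Its camera call was marginal (adjusted p = 0.0498). It was lost with an estimated correlation (adjusted p = 0.492), with library totals as scaling (adjusted p = 0.0505) without line 1.1 JQ1 replicate 2 (adjusted p = 0.0533) and with the Gm42418 covariate (adjusted p = 0.0576).

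Genes of B cell identity fell together. All 23 measured B cell transcription factors passed the threshold, 19 lower and 4 higher. Myb fell by 1.79 ± 0.041, Mef2c by 1.43, Irf4 by 1.15 and Ikzf1, which encodes Ikaros, by 1.14 on the log2 scale. Of 26 genes of the B cell receptor and its coreceptors, 20 fell and 4 rose. The inhibitory coreceptor genes Cd22, Fcgr2b and Cd72 fell by 1.59, 1.42 and 1.19, and Blnk, an adaptor of the receptor, by 1.26. Of 10 early B cell genes, 8 fell and 1 rose, including Rag1 and Rag2, the recombinase of antigen receptor genes, which fell by 2.65 ± 0.058 and 2.61 ± 0.11, and Cd93 (-1.31). Of 6 plasma cell markers, 5 fell and 0 rose, with Slamf7 at -1.80, Sdc1 at -0.55 and Mzb1 at -0.35. The 4 lists passed in camera with adjusted p of 2.18e-07, 2.18e-07, 1.89e-05 and 0.0015. With an estimated correlation the adjusted p was 0.085, 0.14, 0.085 and 0.085. 

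Receptors for cytokines, chemokines and homing signals showed the same direction, with 14 of 20 lower and 3 higher (camera adjusted p = 5.53e-05, and adjusted p = 0.184 with an estimated correlation). Besides Il7r these were led by Ccr7, which guides lymphocytes to lymph nodes (-1.77) and the integrin gene Itga4 (-1.43). NF-kB genes did not move as a group, with 6 of 14 higher and 4 lower (camera adjusted p = 0.987). Nfkbie (-0.70), Nfkb1 (-0.65) and Birc3 (-0.58) fell and Icam1 rose. The median of this list was 0.05, its mean -0.03, and its test direction was down.

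Histone genes showed the most uniform rise of any list. Of 68 genes of the histone clusters and linker histones in the file, 21 passed the expression filter. Of these 21, 20 rose and 0 fell, with a median log2 change of 1.44 (camera adjusted p = 2.18e-07, and adjusted p = 0.085 with an estimated correlation). The rise holds for the histone transcripts that these libraries captured and may not hold for histone mRNA in general. H1f0, a linker histone gene that is not tied to DNA replication, rose by 1.67 and Hist2h2be by 1.57. Immediate early genes also rose, 14 of 22 against 4 that fell, with Jund at 1.41, Btg1 at 1.04, Ier5 at 0.97 and Btg2 at 0.78 (camera adjusted p = 0.000121, and adjusted p = 0.085 with an estimated correlation). Btg1 and Btg2 encode proteins that restrain proliferation. Among 14 heat shock genes 8 rose and 2 fell, led by the near-identical pair Hspa1a (2.27) and Hspa1b (2.13), with Hspa8 at 0.51 and Dnajb1 at 0.51 (camera adjusted p = 0.0271, and adjusted p = 0.318 with an estimated correlation). Among 17 ATF4 targets, genes of amino acid supply and stress, 10 rose and 3 fell, including Atf5 (1.30), Sesn2 (1.19), Slc7a5 (0.50) and Atf4 itself (0.42) (camera adjusted p = 0.0198, and adjusted p = 0.167 with an estimated correlation).

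Regulators of apoptosis moved in opposite directions. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 40.5 ± 0.46 to 133 ± 5.3 CPM in line 1.1 and from 47.1 ± 0.37 to 132 ± 5.3 CPM in line 1.2 (SD, n = 2), by 1.60 ± 0.043 on the log2 scale (SE, edgeR adjusted p = 1.02e-19). The pro-apoptotic gene Pmaip1 rose by 0.46 ± 0.064. The pro-apoptotic genes Bmf and Bak1 fell by 0.89 and 0.55, and the survival gene Bcl2 by 0.35 ± 0.061. In all, 4 of 12 genes of this family rose and 4 fell (camera adjusted p = 0.811). The median and mean were -0.01 and the test direction was up. Of 19 p53 targets, 7 rose and 6 fell, with Sesn2, Btg2 and Ddit4 (0.61) among the risers. The list did not pass (camera adjusted p = 0.497), and its median of -0.10 and mean of 0.22 differed in sign.

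Housekeeping groups changed little in size. Of 85 ribosomal protein genes, 56 rose and 1 fell with a median of 0.10, such as Rps2 (0.29), Rps20 (0.24), Rplp0 (0.24) and Rps12 (0.21) (camera adjusted p = 4.54e-05, and adjusted p = 0.336 with an estimated correlation). The median was 0.05 with library totals as scaling. Of 21 mitochondrially encoded genes, 7 rose and 0 fell, with a median of 0.05 (camera adjusted p = 0.167, but 0.0348 without line 1.2 JQ1 replicate 1, and adjusted p = 0.695 with an estimated correlation and all libraries). The calls of mt-Co1 (0.07), mt-Nd5 (0.08) and mt-Nd4l (0.09) were lost with library totals or upper-quartile scaling, and that of mt-Rnr2 (0.19) with DESeq2. With the Gm42418 covariate mt-Rnr2 was at -0.02, and mt-Co1, mt-Nd5 and Itgam (-0.27) lost their calls. Of 32 genes of DNA replication and mitosis, 11 rose and 15 fell (camera adjusted p = 0.299). Tk1 (-0.72), Plk1 (-0.51) and Mcm3 (-0.50) fell and Rrm2 rose (0.41). Among the markers of other cells, Cd2 (-1.36) and Pecam1 (-2.07 ± 0.056) fell, the myeloid gene Cd68 rose (1.74) and Mrc1 (-1.81), Fcgr3 (-1.15) and Itgam (-0.70) fell. Itgam, at a mean of 1.06 CPM, also lost its call with DESeq2, at a threshold of 0.01, against a fold change of 1.5 and in 6 of the 8 fits that left out a library. Cd6 was at -0.52 ± 0.38 on average and did not pass. It fell in line 1.1, from 12.5 to 4.66 CPM (-1.43, edgeR adjusted p = 2.39e-07), and was near the floor in line 1.2, at 0.305 and 0.398 CPM. An additive model gave -1.32 and called it. The 4 myeloid genes did not pass as a list (camera adjusted p = 0.612).

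**Figure D2:**
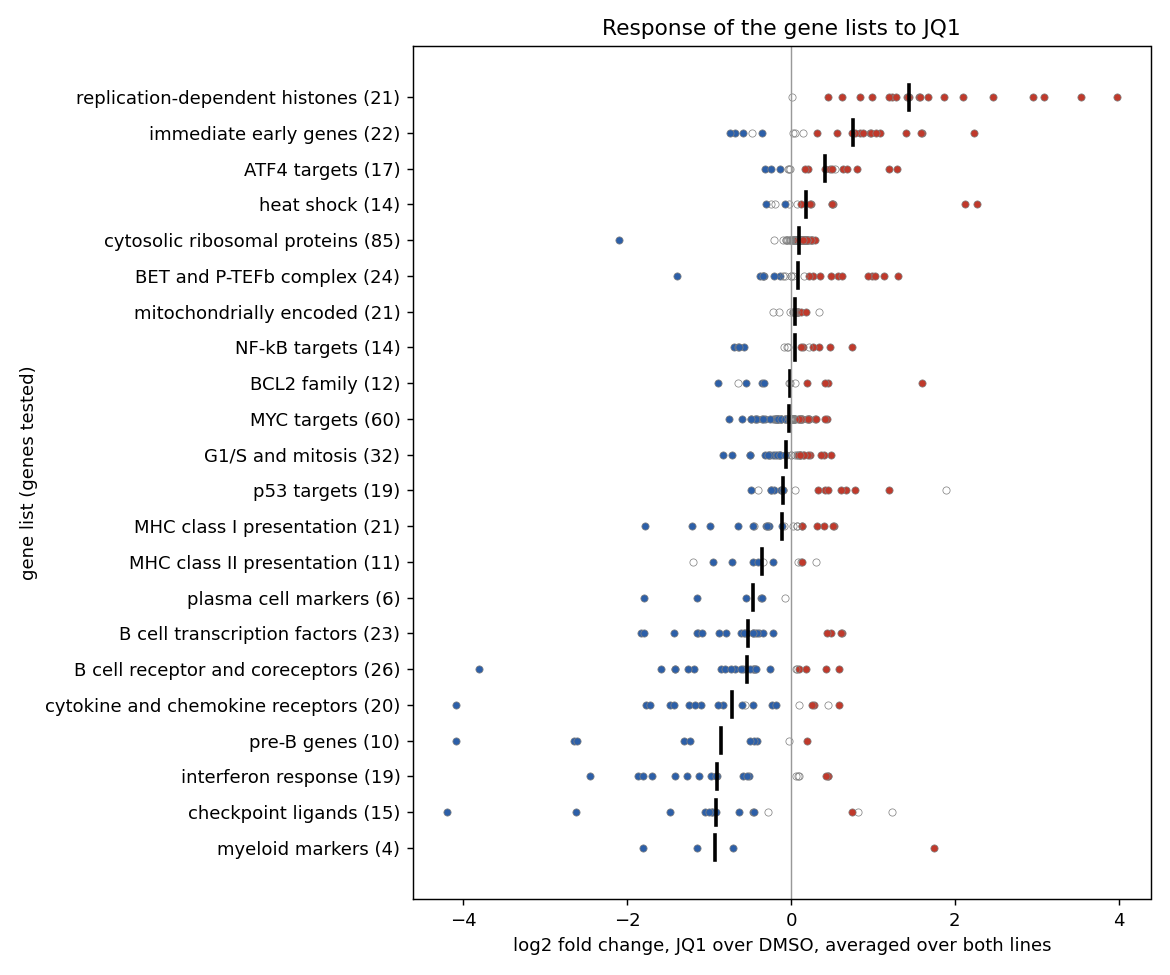
Log2 fold change of each measured gene (points) in the 22 gene lists tested, JQ1 over DMSO, averaged over both lines. Filled points passed the threshold of 0.05 (red higher, blue lower), open points did not, and black bars are list medians, from 1.44 for histones to -0.93 for the 4 myeloid markers.

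Of the 22 lists tested, 13 passed in camera with the preset correlation, 6 higher and 7 lower, and none passed with an estimated correlation. The estimate for the checkpoint ligands was -0.00805, below the preset 0.01, yet their unadjusted camera p went from 0.000839 to 0.0235. Estimates were also below the preset for interferon response genes, immediate early genes and plasma cell markers, and above it for the other lists that passed. A call lost in that run thus does not by itself show correlated members. Adjusted over the list alone, the counts were as above except for immediate early genes (15 higher, 4 lower), heat shock genes (9 higher, 2 lower) and mitochondrially encoded genes (1 higher, 0 lower).

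The next comparisons asked whether JQ1 acts alike in both lines. In line 1.1, 6334 genes passed, 3096 higher and 3238 lower. In line 1.2, 6136 passed, 3031 higher and 3105 lower. With the level of Gm42418 as a covariate, an alternative added after seeing the data, 2908 genes passed in line 1.2. Gm42418 was highest in both JQ1 libraries of that line, so the covariate overlaps this group. The log2 changes of the lines, which share no library, correlated across the 12413 genes with a Pearson coefficient of 0.853 and a Spearman coefficient of 0.829, and with 0.942 and 0.908 over genes with a mean of at least 5 CPM. With the Gm42418 covariate the Spearman coefficient was 0.685. Genes are not independent replicates, so no p is given. The lines shared their most abundant heavy chain and kappa variable genes (below), so they may be related. In both lines, 2419 genes rose, against 756 for independent lists, and 2566 fell, against 810. Opposite calls were made for 5 genes. Tspoap1, Hist1h1c, Il7r, Thbd, Rag1, Hexim1 and Bcl2l11 each passed in both lines in the same direction. The 13 lists named above passed in camera in each line with the preset correlation. With an estimated correlation none passed in either line, the lowest adjusted p being 0.1 in line 1.1 and 0.0701 in line 1.2. In line 1.1 the MYC targets (median -0.06, adjusted p = 0.0383, and adjusted p = 0.669 with an estimated correlation) and the mitochondrially encoded genes (median 0.11, adjusted p = 0.00973, and adjusted p = 0.46 with an estimated correlation) passed too.

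A test of the difference itself, the interaction of line and drug, found 14 genes, 10 with a higher and 4 with a lower JQ1 effect in line 1.2. At an unadjusted p under 0.05 there were 1000 genes of 12413. A share of 0.05 of the genes tested would fall there with no difference in any gene. The largest difference among named genes was that of Plxnc1, a semaphorin receptor gene. It rose in line 1.1 from 158 ± 3.9 to 449 ± 4.9 CPM and was at 6.5 ± 0.76 and 5.12 ± 0.4 CPM in line 1.2 (SD, n = 2), a difference of -1.85 ± 0.17 on the log2 scale (SE, edgeR adjusted p = 8.39e-07). Scml4 fell in line 1.2 (-1.94 ± 0.20) and was at -0.24 ± 0.15 in line 1.1, a difference of -1.71. Tspoap1 rose in both, by 5.04 in line 1.1 and 3.99 in line 1.2. Rbm34 rose more in line 1.2 (1.89 against 1.42), while Adam19 (-0.98 against -1.57) and Ankrd37 (-0.82 against -1.95) fell less there. Iglv1 fell more in line 1.2 (-1.44 against -0.80). Bhlhe41 fell in line 1.1 (-0.41 ± 0.067) and was at 0.049 ± 0.064 in line 1.2, and Mir6240 rose in line 1.2 (1.26 ± 0.13) and was at 0.27 ± 0.13 in line 1.1.

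The number of interaction calls depended on single libraries. It was 459 without line 1.1 DMSO replicate 1, 44 without line 1.1 DMSO replicate 2, 8 without line 1.1 JQ1 replicate 1, 8 without line 1.2 DMSO replicate 1 and 9 without line 1.2 JQ1 replicate 2. It was 6 with DESeq2, 80 with no filter on low counts, 8 with the stricter filter and 2 against a fold change of 1.5. With Gm42418 as a covariate it was 8 (2 higher, 6 lower), and the calls of 7 named genes ended. Of these, Scml4 (-1.92), Rbm34 (0.41) and Mir6240 (0.81) kept differences of similar size, while those of Tspoap1 (-0.77), Ankrd37 (0.73), Bhlhe41 (0.25) and Iglv1 (-0.19) became smaller. No member of the gene lists passed the interaction test. In camera with the preset correlation, the mitochondrially encoded genes (median difference -0.14) and ribosomal protein genes (-0.05) had a lower JQ1 effect in line 1.2 and the MYC targets (0.07), B cell transcription factors (0.10), B cell receptor genes (0.12) and ATF4 targets (0.08) a higher one. With an estimated correlation none passed, with adjusted p of 0.42, 0.631, 0.631, 0.42, 0.631 and 0.42 in this order.

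**Figure D3:**
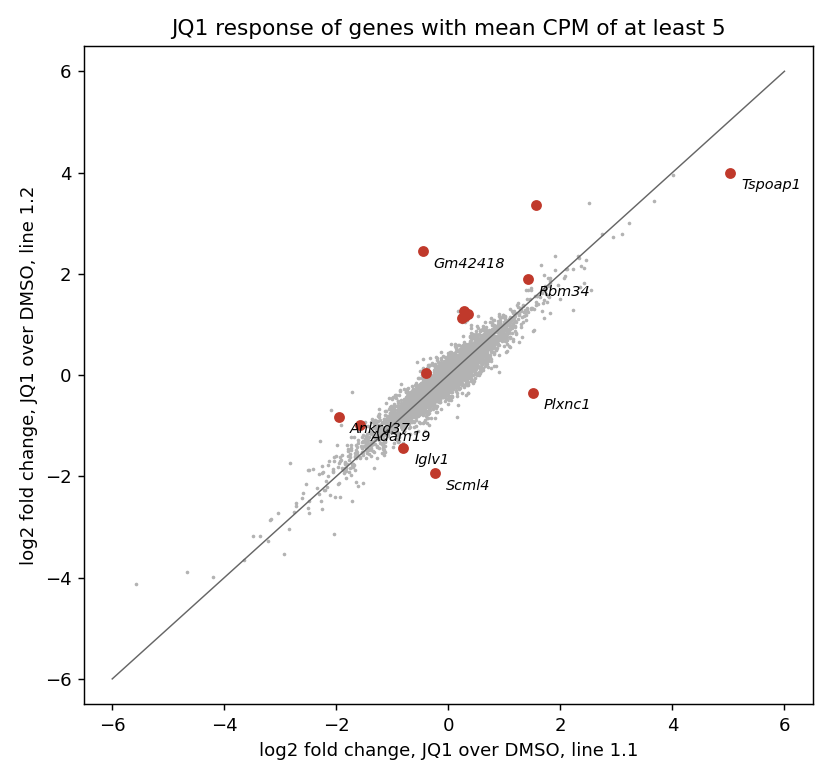
Log2 fold change of JQ1 over DMSO in line 1.1 (horizontal) and line 1.2 (vertical) for 9384 genes with a mean of at least 5 CPM. Red points are the 14 genes whose effects differed at the threshold of 0.05 and the grey line marks equal effects, with Plxnc1 far below it.

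The last comparison described how the lines differ without drug. In DMSO, 840 genes (6.77%) differed, 446 higher and 394 lower in line 1.2, and 91 and 59 of these at least 2-fold. Immunoglobulin light chain genes were among the largest differences in both directions. The kappa variable gene Igkv12-46 was at 26.2 ± 0.48 CPM in line 1.2 and 0.591 ± 0.024 CPM in line 1.1 (SD, n = 2), a log2 difference of 5.44 ± 0.19 (SE, edgeR adjusted p = 1.67e-16). Igkv3-3, Igkv3-5, Igkv3-9 and Igkv3-10 were higher in line 1.2 by 4.04, 3.23, 2.68 and 2.49. The lambda variable gene Iglv1 was at 754 ± 92 CPM in line 1.1 and 47.5 ± 0.029 CPM in line 1.2, a difference of -3.99 ± 0.070, and Iglv2 differed by -3.83. The survival gene Bcl2 was 6.04-fold higher in line 1.2, at 108 ± 5.3 against 17.8 ± 0.2 CPM, a log2 difference of 2.60 ± 0.076 (edgeR adjusted p = 2.95e-18). Plxnc1 differed by -4.60, Mical3, which encodes an actin-oxidising enzyme, by -3.06, Hadh, an enzyme gene of fatty acid oxidation, by -2.85 and Bahcc1 by -2.58, all lower in line 1.2.

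The count of line differences was 1318 without line 1.1 DMSO replicate 1, 388 without line 1.2 DMSO replicate 1 and 313 without line 1.2 DMSO replicate 2. It was 291 with DESeq2, 445 from the 4 DMSO libraries alone, 376 at a threshold of 0.01 and 87 against a fold change of 1.5. The balance of directions was not stable, with 590 higher and 728 lower without line 1.1 DMSO replicate 1, 525 and 589 without line 1.1 DMSO replicate 2, 423 and 432 with DESeq2's size factors and 508 and 336 with library totals.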

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

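The fits without single libraries were chosen beforehand, but their use as a test of 1 deviating library was chosen after the result was seen, as was the bound used for genomic DNA, which replaced an earlier one (no increase at all) after its value was known. The tests of structured RNA and of intronic RNA were written before.

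The JQ1 effect differed between the lines, by the interaction test, for 14 genes. The differences (line 1.2 minus line 1.1, log2) were -1.85 for Plxnc1, -1.71 for Scml4, -1.04 for Tspoap1, -0.63 for Iglv1, 0.59 for Adam19, 0.47 for Rbm34, 0.46 for Bhlhe41, 1.13 for Ankrd37 and 0.99 for Mir6240. The other 5 fall outside the rule for named genes and were chosen after their values were seen: Gm42418 (2.91), which overlaps ribosomal RNA sequence, Gm26397 (1.79), a small nucleolar RNA gene, and Gm24187 (0.88), Gm24270 (0.87) and Gm24245 (0.85), annotated as microRNA genes.

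Whether 1 deviating library produced the differences was weighed for the 8 genes other than small-RNA and ribosomal ones. Over the 8 fits that left out a library, the highest adjusted p of any of them was 0.715, and the lost calls did not come from 1 particular library, so this stays open. Gene by gene, Plxnc1, Scml4, Tspoap1, Adam19 and Rbm34 passed in all 8 fits, Ankrd37 in 4, Bhlhe41 in 3 and Iglv1 in 2, a division read off the same fits and not tested apart from them. Most differences stayed of similar size where the call was lost, with Iglv1 at -0.57 to -0.70, Bhlhe41 at 0.36 to 0.5 and Ankrd37 at 0.74 to 1.14. Of these 8, only Plxnc1 and Adam19 kept their calls with Gm42418 as a covariate (8 genes passed in all, chosen after seeing the data). Scml4 (-1.92) and Rbm34 (0.41) kept differences of similar size there, so the lost call does not show that they went away.

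The 6 small-RNA and ribosomal genes were weighed apart. Gm42418 was at 1300 and 2640 CPM in the line 1.2 JQ1 libraries, at 977 CPM in line 1.1 DMSO replicate 2 and at 341 to 493 CPM in the other 5. If structured RNA differed in amount between single libraries, the other 5 genes would follow Gm42418 between replicates. In the 2 groups whose replicates differed most in Gm42418 (by 1.43 and 1.03 log2), their mean difference in its direction was 0.11, and 6 of 10 values were above 0. That is too weak to decide. The test left out line 1.2 DMSO, whose replicates differed by -0.17 log2 in Gm42418. There Mir6240 was at 56.4 ± 23, Gm24270 at 36.3 ± 13, Gm24245 at 34.7 ± 10, Gm24187 at 29.9 ± 9.5 and Gm26397 at 2.77 ± 0.046 CPM (SD, n = 2). All but Gm26397 thus varied between these replicates with little change of Gm42418. A carry-over of such RNA and a line difference cannot be told apart for these 6 genes.

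The share of reads assigned to no gene, which no comparison of the report uses, was higher in the JQ1 libraries. It was 14.2% ± 0.16 in the 4 JQ1 libraries and 12.8% ± 0.39 in the 4 DMSO libraries (SD), a difference of 1.41 percentage points (exact permutation test within lines, 36 arrangements, two-sided p = 0.0556, the smallest it can give), with all 4 JQ1 libraries (14 to 14.4%) above all 4 DMSO libraries (12.3 to 13.1%). A permutation of all 8 libraries, chosen first and without regard to line, gave an exact p of 0.0286. The test within lines was added after the result was seen. Genomic DNA would also raise reads at silent genes. Spread evenly, it would add 27.7 CPM (here of all reads in the file) at 1654 silent olfactory and vomeronasal receptor genes, and the increase found was 0.0334 ± 0.31 (SE), which argues against it. Intronic RNA would raise genes annotated inside introns, of which 26.7% (4 of 15) had a log2 change above 0 (exact binomial p = 0.118). With 15 genes this does not decide, so more intronic or other unannotated transcription after JQ1 stays open.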

How the results depend on the processing

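The counts for the averaged JQ1 effect and for each line stayed within 1.5 times under every alternative, with the following exceptions. With Gm42418 as a covariate, chosen after seeing the data, the line 1.2 count was 2908. The averaged and line 1.1 counts (6188 and 6598) stayed within 1.5 times there. This covariate overlaps the line 1.2 JQ1 group. The test against a fold change of 1.5 called 1458, 1184 and 1082 genes (averaged, line 1.1, line 1.2) because small changes cannot pass it. Library totals as scaling left 42.6% of averaged calls higher, against 49.5%. Without 1 library these counts were 7029 to 7817, 4939 to 6260 and 4827 to 6771. Leaving out a library leaves its group with 1 library, which is assumed to vary like the other groups. The interaction count of 14 was 6 with DESeq2, 80 with no filter, 8 with the stricter filter, 2 against a fold change of 1.5, 7 at a threshold of 0.01, 8 with the Gm42418 covariate and 8 to 459 without 1 library. The line difference of 840 genes in DMSO was 291 with DESeq2, 445 from 4 libraries, 87 against a fold change of 1.5, 376 at a threshold of 0.01, 759 with the Gm42418 covariate and 313 to 1318 without 1 library. A stricter threshold or a fold bound calls fewer genes by construction, and the cause of the other shifts was not tested. The Spearman correlation between the lines was 0.829 with library totals and 0.685 with the Gm42418 covariate.

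The replicate numbers showed little sign of pairing the samples. Deviations of same-numbered libraries correlated at -0.03 to 0.078, and at 0.0063 and 0.016 within a line. These correlations cover all genes tested, where counting noise of low genes can hide a shared batch, so pairing is not excluded. The interaction count, 14 without a block, was higher with either block. With the number as a replicate block the counts were 7709, 6361, 6148, 26 and 872 (averaged, line 1.1, line 1.2, interaction, line), and with a replicate block within line 7816, 6507, 6294 and 63 (averaged, line 1.1, line 1.2, interaction).

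Of the gene lists, 13 passed, 0 with an estimated correlation, 18 with fry, which does not compare a list with other genes, 12 with the Gm42418 covariate and 12 to 14 without 1 library. Over 22 alternatives, the 133 results on named genes gave 2768 values, of which 2644 kept direction and side of the threshold, 122 lost the call, 1 gained it (Cd6, additive model) and 1 reversed (mt-Rnr2, -0.02 with the Gm42418 covariate). The test against a fold change of 1.5 ended more calls than any other alternative. For single lists, 285 of 308 values kept their side, 16 lost and 7 gained it. Depth limits genes such as Cd274, with 7 to 40 reads per library.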

Other observations

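The immunoglobulin genes described the lines further. Ighv10-1 was the most abundant heavy chain variable gene in all 8 libraries, with 80.9 to 82.8% of heavy chain variable reads in line 1.1 and 81.2 to 82.6% in line 1.2, and its level did not pass the test of a line difference (log2 difference 0.10, edgeR adjusted p = 0.288). Ighv1-28, annotated as a variable pseudogene and so outside the class of variable genes below, behaved likewise (0.13, adjusted p = 0.473). Igkv3-4 was the most abundant kappa variable gene in all 8 libraries. It held 70.1 to 82.5% of kappa variable reads in line 1.1 and 72.8 to 75% in line 1.2. Light chain levels differed: Igkv3-4 was 5.36-fold, the kappa constant gene Igkc 2.66-fold and the lambda constant gene Iglc2 2.36-fold higher in line 1.2. Iglv1 held 95.4 to 96.3% of lambda variable reads in line 1.1 and 83.3 to 88.2% in line 1.2, where its CPM in DMSO was 0.063 times that of line 1.1. After JQ1, Ighd rose 3.28-fold (log2 change 1.71 ± 0.082), Ighm rose 1.14-fold, Igkc fell to 0.823 and Iglc2 fell by 1.46 on the log2 scale. Of 22 variable genes tested as a class (13 classes, looked at after the results were seen), 14 fell and 1 rose (camera adjusted p = 0.0181, and adjusted p = 0.408 with an estimated correlation). Related variable genes share sequence, so reads of 1 rearranged gene may be counted in its relatives, and the calls on Igkv3 genes beside Igkv3-4 are uncertain. With library totals as scaling the class median was -0.87, against -0.83. Junction sequences were not analysed here, so whether the lines share an origin was not tested.

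Gene families defined by symbol were searched after the results were seen, 65 families of at least 15 protein-coding genes. Beside the histones, 2 passed in camera: genes named Cd, mostly surface molecules, with 28 of 42 lower and 8 higher (median -0.49, adjusted p = 0.00016), and genes named Atp, mostly ATPase and ATP synthase subunits, with 27 of 55 higher and 4 lower (median 0.09, or 0.05 with library totals, adjusted p = 0.0356). With an estimated correlation each had an adjusted p of 0.812. Mitochondrial ribosomal genes named Mrpl, with 26 of 48 lower and 6 higher, did not pass (adjusted p = 0.0876). Among gene classes, 229 of 929 processed pseudogenes rose and 57 fell (median 0.10, or 0.06 with library totals) and 73 of 227 lincRNA genes fell and 29 rose (median -0.15), without passing in camera (adjusted p = 0.0715 and 0.141). Genomic length showed no trend: protein-coding genes in 5 groups by length, with median spans from 5.12 to 103 kb, had median log2 changes from 0.02 to -0.01.

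The scalings used below were chosen beforehand, but their use as a test of the next pattern, and its other tests, were chosen after the result was seen. Myc mRNA rose by 0.62 after a drug that displaces BET proteins. The rise did not hinge on the choice of scaling, since the lowest value over 3 other scalings was 0.58. These scalings moved the median change of all genes to no lower than -0.04, so a much smaller value was not to be foreseen. All rest on the counts of the same libraries, so a change in total mRNA per cell was not tested. A joint rise of the endogenous gene and its neighbour Pvt1 is argued against, since Pvt1 fell, with a log2 change of -0.86 ± 0.11 (SE). A rise of endogenous Myc without Pvt1 was not tested. A common rise under the immunoglobulin heavy chain enhancer, which drives the transgene, was weighed by other heavy chain genes. Ighm rose by 0.19, the variable gene Ighv10-1 by 0.135 and Ighd by 1.71. Ighm and Ighv10-1 thus rose less than Myc and Ighd more, so these genes did not rise alike. As transgene and endogenous reads are also summed, this hypothesis stays open.

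For the count of genes changed by JQ1, the 8 libraries were split into 4 and 4 in the 34 ways that can be fitted with line in an additive model, a test chosen before the result was seen. Only 1 split, the real one, gave as many genes (7580), and the highest of the others was 0. The other splits keep 2 or 3 JQ1 libraries on a side, which puts the JQ1 effect into their residual, so few calls were to be foreseen there. The 34 splits exclude chance assignment only if libraries can be exchanged across lines. Kept within lines there are 18 splits, too few for a share under 0.05.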
